A study of Mus musculus with 12 samples.

How the data were processed

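RNA was measured in cultured adult mouse dorsal root ganglion neurons with the RiboTag allele and Advillin-Cre, after a conditioning nerve injury and infection with a control or an shLarp1 virus. For each virus, HA immunoprecipitates (IP) and input were sequenced, with 3 columns per group and 12 in all. Per the labels' protocols, libraries were made with a nanopore cDNA-PCR barcoding kit, which carries no molecular identifiers. Per the labels, the RNA source is cultured neurons, whereas the extraction text speaks of lysate from fresh ganglia, and the titles of the control input and control IP samples word the control virus differently. Both wordings were taken as the control virus.

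The deposited table holds estimated counts per gene, in whole numbers and not scaled to depth. The submitters' processing notes name minimap2, Salmon and the builds GRCm39 and mm39. Versions, annotation release, filters and strand use are not given in the sources used here. Per the deposited values, the table has 15391 genes and no gene with fewer than 13 counts over the 12 columns. Reads of overlapping, antisense or near-identical genes cannot be told apart in such a table. Gene symbols came from a table of gene names, matched by identifier: 13711 genes had a symbol and 1680 did not. Gene types came from a RefSeq table of assembly GRCm38.p6, used for names and types only.

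Total counts per column were 3126591 to 3128368 (control IP), 3176458 to 3177552 (shLarp1 IP), 564095 to 564625 (control input) and 759527 to 760140 (shLarp1 input). Genes detected per column were 8134 to 8296 in input and 14999 to 15061 in IP. Before any comparison the 3 columns of a group were set against 3 random parts of their summed counts. Their totals varied less than random parts, and the median chi-square per gene was 1.46 to 1.53 against 1.38 to 1.42, over genes with at least 30 counts. Part of the excess lay in genes that share reads with copies (Rnaset2b, Srp54c, Entpd4b, Fam177a), and part was general: without the top 5% of genes the mean chi-square per degree of freedom was 0.915 to 0.935, against 0.846 to 0.855 in random parts. The labels name no separate cultures or animals for the columns. They were therefore counted as 1 sample per group, which departs from the test planned before the data were examined.

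The main values are counts summed per group, scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, as log2 ratios with an exact (Clopper-Pearson) interval at 95%. For the interaction 0.5 counts were added to each group and the interval is a normal approximation on the log scale. A gene was called higher or lower where the interval lay wholly beyond 1.5-fold. This size rule was chosen after the columns had been compared. Genes with too few counts were removed by filterByExpr (minimum count 10), which left 8773 genes. Of these, 1185 had 0 counts in every input column, and 7588 had input counts. A fold against a group at 0 is a lower bound, computed against 3 counts over the group. It takes the other group's count as measured, so it can exceed the limit of the counting interval. Intervals cover counting error only. No p-value is given for a single gene, because none would compare the conditions.

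The planned test, edgeR's quasi-likelihood test with a group-means model on the 12 columns, Benjamini-Hochberg adjustment and a threshold of 0.05, was also run. The planned test of gene lists, camera in limma 3.58.1, treats the columns as replicates too. It called 37 of 140 tests (28 lists in 5 comparisons), 25 with an estimated correlation. Counts of list members adjusted over the list alone were left out, since they would rest on the same p-values. Instead each list's median was ranked as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Not every percentile is printed. The percentile was computed again among genes outside the low-ratio and zero classes, an alternative chosen after seeing the data. The percentiles describe these samples and do not depend on the scaling of the groups.

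Named genes followed a rule fixed before the data were examined. It takes Larp1, Rpl22, and for IP, input and interaction the 12 largest changes of each direction. These had to pass the planned test, be at or above the median expression, and have no overlap between the columns of the groups (10% of genes have none by chance with 3 against 3; not required for the interaction). For IP over input it takes the 8 largest of each direction with the control virus. It adds up to 4 members per list, or all members where 5 or fewer changed. Genes without a standard symbol were counted and not named. The lower genes outside the low-ratio and zero classes, and the genes repeated across comparisons as examples, were added after their values were seen.

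The size rule, its interval and the planned test for genes were tested on simulated data with the real depths; the tests of gene lists were not. In the IP comparison (8766 genes) the size rule called 26 of 50 genes changed 2-fold and 50 of 50 changed 3-fold. In input (7588 genes) it called 7 and 23 of 50, and in the interaction 8 and 19 of 50. Of unchanged genes it called 0, 5 and 7. The interval held the true ratio for 96.6% of 8773 genes in IP over input. When 2 simulated samples differed by an assumed coefficient of variation of 10% or 20% and were each split into 3 columns, the planned test called 1536 and 3644 of 8773 unchanged genes and the size rule 7 and 436.

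The alternatives fixed beforehand were DESeq2 1.42.0 (size factors and its own test), upper-quartile and total-count scaling, no filter, a stricter filter (10 counts in at least 9 columns), limma-voom, a replicate block, leaving out each column, fitting the compared groups alone, and for lists fry and an estimated correlation. The size rule under each scaling and filter, a 2-fold bound, and the counts without the low-ratio and zero classes were added after seeing the data.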

Results

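The series measured RNA in cultured adult mouse sensory neurons after knockdown of Larp1, an RNA-binding protein that binds the cap and terminal oligopyrimidine (TOP) tract of mRNAs for ribosomal proteins and translation factors. The neurons came from dorsal root ganglia of mice whose sciatic nerve had been injured before culture, a conditioning lesion that starts a growth program. They carried RiboTag, an HA-tagged ribosomal protein Rpl22 switched on by Advillin-Cre in sensory neurons, so that an antibody against HA pulls down ribosomes of these neurons with their bound mRNA. An adeno-associated virus delivered either a control construct or a short hairpin RNA against Larp1 (shLarp1). Sequencing covered the immunoprecipitate (IP) and the input RNA for each virus on a nanopore platform, giving 4 groups with 3 columns of counts each.

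The IP columns held 3126591 to 3177552 counts each and the input columns 564095 to 760140. Summed over a group, the totals were 9382094 (control IP), 9530760 (shLarp1 IP), 1693039 (control input) and 2279226 (shLarp1 input). The 3 columns of a group differed in their totals by 0.0344% to 0.0939%, and the SD of those totals was below that of 3 random parts of the summed counts in every group, for example 910 against 1440 in control IP. Per gene they differed by about the sampling noise: 6.98% to 7.62% of genes had a chi-square p under 0.05, against 4.55% to 5.3% in random parts. Part of the excess was general, and part lay in genes that share reads with near-identical copies, such as Rnaset2b with 70, 3 and 0 counts in the 3 control IP columns. The labels list the columns as separate samples. Because of their likeness they were counted as 1 sample per group, which the counts alone do not prove, and every value below has n = 1 per group, with a 95% interval that covers counting error only. PCR copies are not independent molecules, and no replicate check exists for any difference between the viruses. A gene is called higher or lower where the whole interval lay beyond 1.5-fold.

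Larp1 itself, the target, was lower with shLarp1. In the IP its summed count went from 442 to 149, a 3.3-fold lower level (log2 -1.72, interval -2.0 to -1.45), and the 3 columns held 147, 141 and 154 counts for the control virus and 55, 49 and 45 for shLarp1. In input the counts were 18 and 8 (log2 -1.37, -2.78 to -0.09), with 5, 7 and 6 against 3, 3 and 2 per column, which did not pass the 1.5-fold rule at this depth. Rpl22, the tagged protein, had 6137 and 6039 IP counts (log2 -0.18, -0.23 to -0.12).

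**Figure D1:**
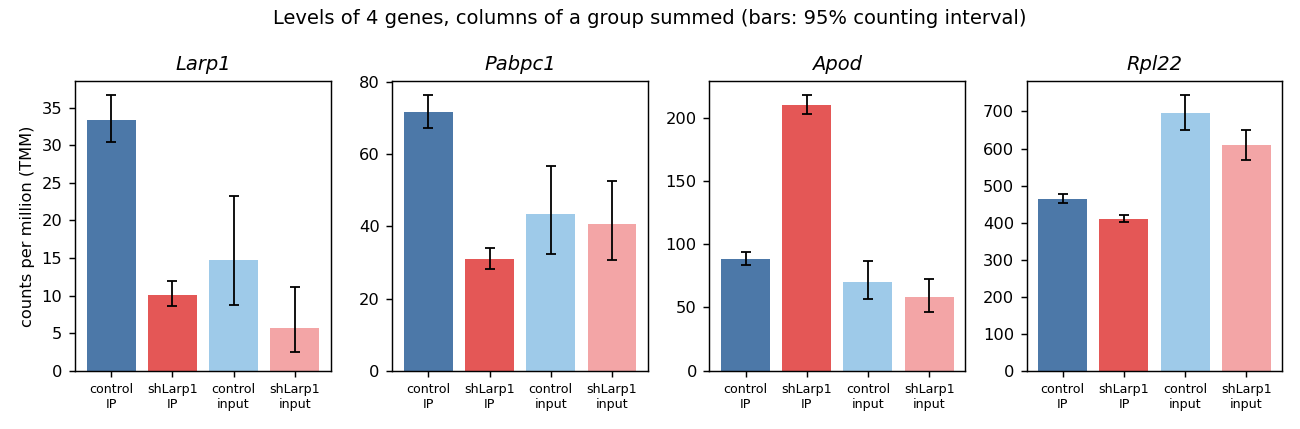
Scaled counts (CPM, TMM factors) (y axis, starting at 0) of Larp1, Pabpc1, Apod and Rpl22 in the 4 groups, with the columns of a group summed and bars for the 95% counting interval. Larp1 and Pabpc1 were lower in the shLarp1 IP than in the control IP (10.1 against 33.4 and 30.9 against 71.8), and Apod was higher (210 against 88.6).

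The first comparison asked which RNAs changed in the IP after Larp1 knockdown. It does not separate mRNA bound to tagged ribosomes from background RNA in the IP. Apod, a secreted lipid-carrying lipocalin, was 2.37-fold higher in the shLarp1 IP (1172 to 3093 counts, log2 1.25, 1.15 to 1.35). Pabpc1, the cytoplasmic poly(A)-binding protein and itself a TOP mRNA, was 2.32-fold lower (949 to 454 counts, log2 -1.22, -1.38 to -1.05). Ybx1, a Y-box RNA-binding protein, was 1.76-fold lower (log2 -0.82, -0.99 to -0.65), and the kinase gene Mapk8 (JNK1) was 2.35-fold lower (log2 -1.23, -1.62 to -0.86). All 13 mRNAs encoded by the mitochondrial genome had values below 0, with a median of -0.67, while no ribosomal protein mRNA passed the 1.5-fold rule. With the control virus these 13 mRNAs lay lower in the IP than in input (median -1.83). Their IP levels therefore need not reflect tagged ribosomes. Across 8766 genes evaluated, 63 were higher and 386 lower. Between 2 simulated samples without changed genes, the same rule called 7 of 8773 genes at an assumed coefficient of variation of 10%. At 20% it called 436, and the true variation between samples is not known here.

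Beside Apod, the genes of the naming rule that passed as higher in IP were Inpp5f, a phosphoinositide phosphatase (log2 0.99, 0.64 to 1.36), Pwp1, a WD-repeat protein (0.99, 0.72 to 1.26), and Ube2f, a NEDD8-conjugating enzyme (0.96, 0.61 to 1.32). A further 8 genes met the naming rule and not the 1.5-fold rule. They included Noct (0.87), the platelet glycoprotein Gp1bb (0.85), Spg7 (0.74), Mboat7 (0.74), the heparin-binding growth factor Ptn (0.72), Farsb (0.69) and the imprinted non-coding Peg13 (0.69). The lower genes named by the rule were, besides Larp1, Tirap (log2 -2.06), Neu3 (-1.94), Zfp710 (-1.94), Pigl (-1.83), the mitochondrial tRNA mt-Te (-1.38), Plin3 (-1.32), S100a2 (-1.31), Grhl2 (-1.30), Mcm10 (-1.29) and Snx32 (-1.27), and Ak9 had -1.32 with an interval of -2.16 to -0.53. Of these, mt-Te had 0 counts in every input column, and all others except Larp1 belonged to the low-ratio genes described next.

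Low-ratio genes (764 genes with a mean log2 ratio of IP to input under -2 over both viruses) and genes at 0 counts in all input columns (1185) moved together in the IP. Their medians were -0.48 and -0.46, against -0.01 in the other 6824 genes, and they held 106 and 184 of the 386 lower genes. The markers of glia, fibroblasts, leukocytes and vessels outside these classes had a median of -0.01 in the IP. Outside these classes 49 genes were higher and 96 lower. The lower ones with the largest changes there, singled out after their values were seen, were besides Larp1, Mapk8 and Pabpc1 the histone methyltransferase Ehmt2 (-1.16), Akap10 (-1.09), Ccni (-1.08), Zfp64 (-1.06), Wdr47 (-1.04), Atad1 (-0.99), the translocon component Sec63 (-0.98), Rrp15 (-0.95) and the mitochondrial ribosomal protein Mrpl1 (-0.90).

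**Figure D2:**
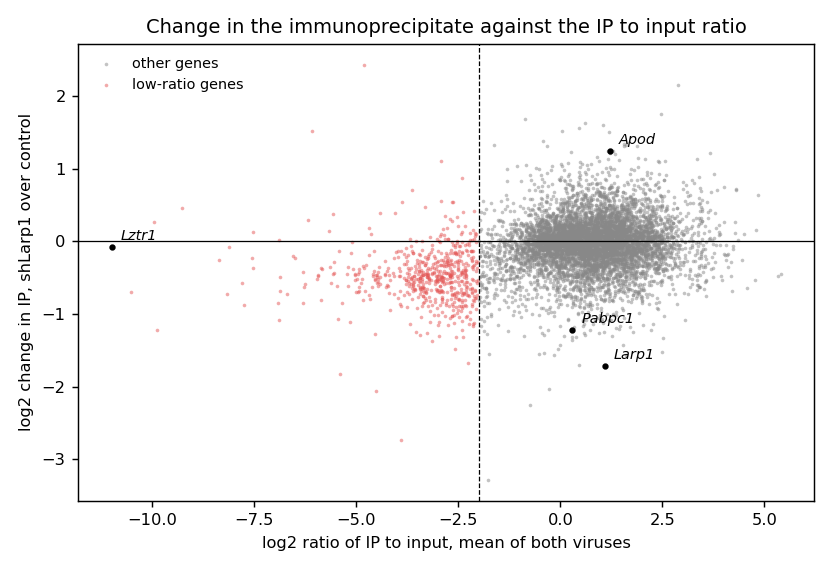
Log2 change in the IP (y axis, shLarp1 over control) against the log2 ratio of IP to input averaged over both viruses (x axis), 1 point per gene with at least 100 IP counts; red points are the genes with a ratio under -2 (dashed line). Most of the red points lie below 0, with a median of -0.48 over all 764 such genes, while the median of the 6824 other genes was -0.01.

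The gene lists fixed beforehand gave the following in the IP, where the median of all genes was -0.08. Of 47 large-subunit and 32 small-subunit ribosomal protein mRNAs, 0 passed in either direction, with medians of -0.14 and -0.17. Among 10000 random lists of like size and expression these medians lay at percentiles 33.0 and 19.8. Among random lists drawn outside the low-ratio and zero classes, none of the 10000 lay lower than either. The lowest-lying abundant members included Rplp1 (-0.46, -0.48 to -0.44) and Rps19 (-0.37, -0.39 to -0.35). Of 31 other TOP mRNAs, Pabpc1 and Ybx1 were lower and 29 did not pass (median -0.11, which became 0.03 with total-count scaling). This median lay at percentile 36.2, and at 2.27 outside the low-ratio and zero classes. Initiation factors and the mTOR pathway had a median of -0.04 with 0 of 28 passing. In the list of LARP proteins and poly(A) tail regulators, Larp1 was lower and 24 of 25 did not pass (median -0.12). The stress granule gene G3bp2 of that list had 0.65 (0.44 to 0.86).

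In log2 terms neuronal lists stayed near the median of all genes in the IP. None of 45 regeneration-associated genes passed (median -0.05), with 21 above 0 and 24 below. Examples of those above 0 were Jun (0.42, 0.28 to 0.56), Sprr1a (0.32), galanin (Gal, 0.31) and neuropeptide Y (Npy, 0.25). None of 45 cytoskeletal, 32 synaptic vesicle, 18 ion channel, 15 subtype or 20 pan-neuronal markers passed, with medians of 0.00, -0.03, -0.09, -0.01 and 0.04. Among random lists the cytoskeletal list lay at percentile 98.79 and the pan-neuronal list at 97.89. Outside the low-ratio and zero classes these were 65.74 and 85.95. The other neuronal lists lay at 43.64 to 75.93 (4.04 to 59.02 outside the classes). Uchl1, a neuronal deubiquitinase, had 0.24 and the neurofilament gene Nefl -0.23. Markers of other cells had medians of 0.00 (Schwann cells and satellite glia, 0 of 20 passing), -0.06 (fibroblasts, Apod alone of 25), 0.04 (macrophages, 0 of 12) and -0.24 (endothelial and mural cells, 0 of 6). Cell cycle genes had a median of -0.27 with 0 of 17 passing. None of the 12 erythrocyte and muscle genes passed the expression filter.

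Among mitochondrial genes, 5 of the 13 mitochondrially encoded mRNAs were lower in the IP: mt-Atp6 (-0.89), mt-Co3 (-0.89), mt-Co2 (-0.75), mt-Nd1 (-0.74) and mt-Co1 (-0.67). None of the 10000 random lists had a lower median, and 10 of the 13 belonged to the low-ratio class. Nuclear genes of oxidative phosphorylation had a median of 0.01 with 0 of 78 passing, and of 76 mitochondrial ribosomal protein genes Mrpl1 alone was lower (median -0.01). Medians were 0.06 for glycolysis (0 of 18 passing), 0.04 for the proteasome (0 of 31), 0.00 for the stress and unfolded protein responses (0 of 25), -0.10 for heat shock and immediate early genes (0 of 16) and -0.15 for the interferon response (0 of 16). They were -0.17 for p53 targets (0 of 17), -0.03 for cholesterol synthesis (0 of 22), 0.04 for lysosome and autophagy (0 of 29) and -0.11 for apoptosis and axon degeneration, where Mapk8 alone of 20 was lower. Among random lists, oxidative phosphorylation lay at percentile 100, the proteasome at 99.64, glycolysis at 98.71 and lysosome and autophagy at 98.27. Outside the low-ratio and zero classes these were 89.44, 86.86, 91.06 and 85.01. Upper-quartile and total-count scaling moved the median of all genes in the IP by 0.13, which turns the sign of the smaller medians, and gave splits of 104 higher to 207 lower and 105 to 204.

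**Figure D3:**
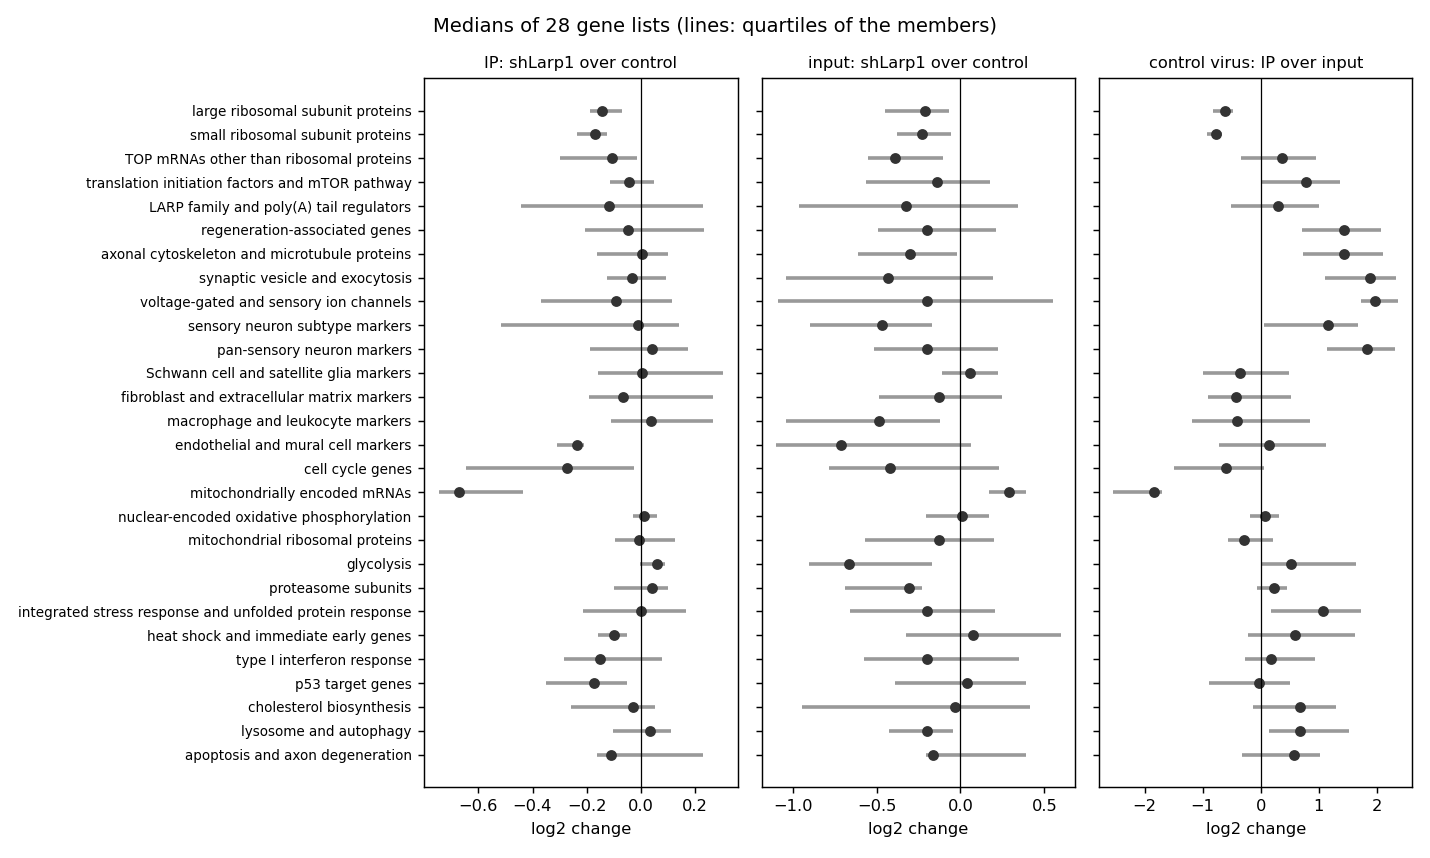
Median log2 change (points) and quartiles of the members (lines) of 28 gene lists, for shLarp1 over control in the IP (left), shLarp1 over control in input (middle) and IP over input with the control virus (right). Mitochondrially encoded mRNAs had medians of -0.67, 0.29 and -1.83, and pan-sensory neuron markers 0.04, -0.20 and 1.83, with TMM scaling. In the middle panel, -0.20 is the value of a gene with equal counts in both inputs.

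The second comparison asked what changed in the input RNA. Glycolysis mRNAs were low in the shLarp1 input: Tpi1 was 2.41-fold lower (log2 -1.27, -1.68 to -0.87), Aldoa 1.99-fold (-0.99, -1.25 to -0.74) and Gapdh 1.89-fold (1804 to 1094 counts, -0.92, -1.03 to -0.81). The median of the 18 glycolysis genes was -0.67, at percentile 0.02 of random lists, and 15 did not pass. Uchl1 was 2.17-fold lower (1772 to 935 counts, -1.12, -1.24 to -1.0), and the translation-associated mRNAs Eef1g and Tpt1 were 2.13-fold and 1.85-fold lower. Across 7588 genes with input counts, 13 were higher and 77 lower.

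The higher genes named by the rule that passed in input were Serp2 (4 to 23 counts, log2 2.33, 0.78 to 4.32), Ppip5k1 (1.21) and Lrrc17 (1.10), the latter with 0 IP counts in both groups. Those named and not passing were Selenot (2.12), Atp6ap1 (1.56), the clathrin light chain Clta (1.47), Phf20 (1.12), Dvl2 (1.11), Immt (1.09), Tmem88b (1.03), Wars2 (1.02) and Mrpl1 (0.96). The lower genes were the phosphate transporter Slc20a1 and Akap2 (each 12 to 2 counts, -2.78, -5.98 to -0.62), Rabif (16 to 3 counts, -2.61, -5.03 to -0.81), Dcaf13 (-2.52), Stoml2 (-2.37), Olfr2 (102 to 23 counts, -2.35), Tsta3 (-2.14), Kdelr1 (-2.12) and the mitochondrial carrier Slc25a39 (-2.09). Nlgn2, a postsynaptic adhesion molecule, had 6 and 0 counts, at least 2.29-fold lower against a floor of 3 counts over the group; its counting interval ended at log2 -0.43, so it did not pass. Neither did Tmem59l (-2.10) or Ppp6c (-1.96). Apod had 86 and 82 counts in input (-0.27, -0.72 to 0.19).

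By list, with the median of all genes at -0.14 in input, Rpl3 (-0.88), Rpl10 (-0.90) and Rplp0 (-0.71) were lower among 47 large-subunit proteins (median -0.21) and Rps12 (-0.67) among 32 small-subunit proteins (-0.23). These medians lay at percentiles 0 and 0.08, and at 0.38 and 2.86 outside the low-ratio class. Several other lists lay low in input too. The cytoskeleton lay at 0.22 (1.555 outside the class), other TOP mRNAs at 0.39 (4.175), synaptic vesicle genes at 0.66 (2.05) and the proteasome at 1.305 (9.7). Oxidative phosphorylation lay at 45.69, and at 99.83 outside the class. Eef1g and Tpt1 were lower among 26 other TOP mRNAs (median -0.39). The vacuolar ATPase subunit Atp6v0c (-1.07) was lower among 32 synaptic vesicle genes (-0.43), osteopontin (Spp1, -1.04) among 15 subtype markers (-0.47), and Uchl1 among 20 pan-neuronal markers (-0.20). Ndufv1 (-1.89), Sdhd (-1.38) and Atp5f1 (-1.02) were lower among 78 nuclear oxidative phosphorylation genes, whose median was 0.01. Psmc6 (-1.85) was lower among 31 proteasome subunits (-0.31) and Fdps (-1.05) among 22 cholesterol genes (-0.03). No member passed in the other lists. Their medians were -0.14 for initiation factors, -0.33 for LARP proteins, -0.20 for regeneration-associated genes, -0.30 for the cytoskeleton and -0.20 for ion channels. They were 0.06 for glia, -0.13 for fibroblasts, -0.48 for macrophages, -0.71 for vessels, -0.42 for the cell cycle, 0.29 for mitochondrially encoded mRNAs and -0.13 for mitochondrial ribosomal proteins. They were -0.20 for the unfolded protein and interferon responses and for lysosomes, 0.07 for heat shock, 0.04 for p53 targets and -0.16 for apoptosis. With this scaling, a gene with equal counts in both inputs has a log2 value of -0.197. Every list median printed here as -0.20 is that value and is not a measured decline. Input counts were low, with a median of 2 per gene in each input group over all genes, those at 0 included.

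The direction of the input comparison depended on the scaling. The low-ratio genes took 56.4% of control input counts and 65.5% of shLarp1 input counts. Their median was 0.43 in input against -0.20 for other genes, the value of equal counts in both inputs. DESeq2 size factors moved the median of all genes by 0.21 and gave 181 higher and 35 lower genes, upper-quartile factors 117 and 43, total counts 7 and 204. TMM with a control IP column as its reference gave 214 and 29. When any of the 6 input columns was left out, TMM took a shLarp1 IP column as its reference (229 to 248 genes passing). Changes in input are therefore to be read relative to the median of all genes. Glycolysis kept a median below 0 under all 3 other scalings (-0.46, -0.52 and -0.90).

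The third comparison asked which genes changed differently in the IP than in input, as the interaction of virus and fraction. Apod was 2.85-fold higher in the IP relative to its change in input (log2 1.51, 1.07 to 1.96). Glycolysis genes lay high: Tpi1 had 1.29, Gapdh 1.15 (1.04 to 1.26) and Aldoa 1.06, each with a lower input level and little change in the IP. The glucose transporter Slc2a3, a low-ratio gene, was lower (-1.40). The median of the 18 genes was 0.83, above all 10000 random lists. Mitochondrially encoded mRNAs lay low, with 8 of 13 lower, a median of -0.89 and mt-Co3 at -1.09 (-1.20 to -0.99). Larp1 had -0.40 (-1.60 to 0.80).

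Over 7588 genes, 105 were higher and 423 lower in the interaction, and 356 of the lower ones were low-ratio genes (median -0.90 against 0.16 in other genes). Named higher genes that passed were Dcaf13 (2.35), Tsta3 (2.31), Olfr2 (2.30), Tmem59l (2.23), Stoml2 (2.18), Abcf2 (2.15), Ppp6c (2.13), Nop16 (1.95) and Tmem199 (1.88). Akap2 (2.49, 0.51 to 4.47), Rabif (2.24, 0.56 to 3.92) and Nlgn2 (0 shLarp1 input counts) did not pass. Named lower genes that passed were Tirap (-2.49), Zfp710 (-2.35), Neu3 (-2.28), Serp2 (-2.27), Pigl (-2.19), LTO1 (-2.07), Ppp4r2 (-2.06), Mcm10 (-2.03), Nudcd1 (-1.98) and Ppip5k1 (-1.94). All of these except Serp2, LTO1 and Ppp4r2 were low-ratio genes. Mgea5 (-2.35, -4.33 to -0.37) and Mbd3 (-2.32, -4.06 to -0.58) did not pass.

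By list, Rpl10 (0.87) and Rpl6 (0.71) were higher among the 47 large-subunit proteins (median 0.03) and none of the 32 small-subunit proteins passed (0.06). Tpt1 (0.88) and Btf3 (0.83) were higher and Ybx1 (-1.37) lower among 26 other TOP mRNAs. The proteasome subunits Psmc6 (1.68), Psmc1 (1.08), Psma1 (1.04) and Psma5 (0.94) were higher (median of 31, 0.43). Ndufv1 (1.74), Sdhd (1.55), Atp5f1 (1.05) and Atp5c1 (0.86) were higher among 78 oxidative phosphorylation genes (0.00). Neuronal genes that passed as higher were Uchl1 (1.36, 1.24 to 1.47), Atp6v0c (1.21), Spp1 (1.14) and the stathmin Stmn3 (0.76), and the regeneration-associated Stat3 was lower (-1.05). Mrpl4 (1.45) was higher and Mrpl1 (-1.85) and Mrpl13 (-1.04) lower among 76 mitochondrial ribosomal proteins. Mapk8 (-1.57) and Nmnat1 (-0.82) were lower in the axon degeneration list. Pmvk (1.26) and Fdps (1.01) were higher and Msmo1 (-0.81) and Srebf2 (-0.76) lower among 22 cholesterol genes. Single lower members were the myelin gene Mag (-1.17), Fn1 (-0.89), Xaf1 (-1.11) and Rrm2b (-1.01), and the mRNA decay genes Xrn1 (-1.40) and Pan3 (-0.95) were lower too. Of these lower members, Mrpl13, Nmnat1, Msmo1, Srebf2, Mag, Fn1, Xaf1, Rrm2b, Xrn1 and Pan3 were low-ratio genes.

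The split in the interaction followed the scaling as well, with 47 higher and 553 lower under DESeq2 size factors, 94 and 436 under upper-quartile factors, and 401 and 138 under total counts. The median of all genes, 0.07 with TMM, moved by -0.20, -0.02 and 0.36. The macrophage list had a median of 0.66 with 0 of 12 passing, at percentile 98.7 (98.2 outside the low-ratio class), and the cytoskeleton list 0.30 at percentile 99.9 (97.9). The medians of the ribosomal protein lists turned negative with DESeq2 size factors (-0.17 and -0.14).

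The comparison of IP with input for the control virus asked how far the IP was enriched for neuronal mRNA. Neuronal mRNAs were higher in the IP: the tubulin Tubb3 4.82-fold (log2 2.27, 2.09 to 2.45), the neurofilament Nefl 9.05-fold (3.18, 2.84 to 3.54), peripherin (Prph) 6.25-fold (2.64) and the GDNF receptor Ret 7.98-fold (3.00, 2.33 to 3.75). Of 20 pan-neuronal markers 14 were higher and 0 lower, with a median of 1.83. Markers of other cells were mixed and lay lower, such as the glial genes Cryab (3.86-fold lower, -1.95) and Fabp7 (2.88-fold, -1.52) and the matrix genes Sparc (4.28-fold, -2.10) and Timp1 (2.90-fold, -1.53). Across 7588 genes 970 were higher and 1095 lower.

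Synaptic vesicle genes were higher for 18 of 32 (median 1.88), with Syt4 at 2.70 and Vgf at 2.54. Ion channels were higher for 7 of 18 (1.97), with Scn10a at 2.54 and Cacnb3 at 1.97. Cytoskeletal genes were higher for 32 of 45 (1.43), including Stmn2 at 1.27. Regeneration-associated genes were higher for 24 of 44 and lower for 3 (1.43), with Sprr1a at 2.58, the injury factor Atf3 at 2.52, Hspb1 at 1.67, Tubb2b at 1.47, Gap43 at 1.23 and Tnfrsf12a at -1.23. Among 15 subtype markers, those higher included Ret, Gfra3 (1.84) and Gfra1 (1.40), and Ntrk3 (-2.37) was lower. Of 20 glial markers, Glul (2.16) and S100b (1.34) were higher and Mag (-6.14), Cryab and Fabp7 lower (median -0.35). Of 12 macrophage markers, Coro1a (1.63) was higher and C1qb (-1.65), Fcer1g (-1.24), Tyrobp (-1.07) and Lyz2 (-1.01) lower (-0.40). Of 25 fibroblast markers 4 were higher and 5 lower (-0.42), and of 17 cell cycle genes 1 was higher and 6 lower (-0.60).

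Ribosomal protein mRNAs were lower in the IP than in input for 23 of 47 large-subunit and 25 of 32 small-subunit genes, with medians of -0.62 and -0.76 and Rplp1 and Rpl39 both at -1.19. Among random lists these medians lay at percentiles 31.18 and 11.61 (0.02 and 0 outside the low-ratio class). IP and input may have been counted against different references, as described below. Whether this shifted the ratios of genes that share reads with copies was not tested. Of the other TOP mRNAs, Eif2s3x (3.22, 1.34 to 6.27), Cct4 (2.12), Eif4a2 (1.23) and Eef2 (1.03) were higher and Tpt1 (-2.44) lower. Mitochondrially encoded mRNAs were lower for 12 of 13 (median -1.83), with mt-Nd2 at -3.05 and mt-Co3 at -1.83. The higher genes named by the rule were Bbs1 (6524 IP and 15 input counts, 40.2-fold) and 7 genes with 0 input counts, for which the fold is a lower bound against 3 counts over the group and the limit of the counting interval is somewhat lower. These were Spock1 (at least 7.89-fold higher, interval from log2 2.67), Eno1b (7.42), Fam89a (6.13), Lmo7 (5.70), Nrip3 (5.64), the beta-secretase Bace1 (4.96) and Ahcyl1 (4.44). Eno1b is a near-identical copy of the enolase gene Eno1, so its reads are uncertain. The lower genes were Akap5 (at least 2009-fold lower, interval to log2 -10.7), Mcmdc2 and Lrrc17 (each at least 938-fold, to -9.56), all at 0 control IP counts, and Rep15 (log2 -11.4), Lztr1 (-10.7), the channel gene Trpm2 (-9.91), Hlcs (-9.76) and Rab33b (-9.24). Lztr1 alone took 2.64% of control input counts and 3.22% of shLarp1 input counts.

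The level of the IP against input was set by the scaling, with 1149 higher and 1021 lower genes under DESeq2 size factors, 394 and 1590 under upper-quartile factors, and 3376 and 651 under total counts. The median of all genes moved from 0.38 to 0.48, -0.11 and 1.36. With total counts the medians of the glial, fibroblast, macrophage and ribosomal protein lists were above 0 (0.63, 0.56, 0.58, 0.36 and 0.22) and below the median of all genes.

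With shLarp1, neuronal mRNAs were also higher in the IP than in input. Tubb3 was 7.92-fold higher (log2 2.98, 2.76 to 3.22), Nefl 6.21-fold (2.63), Prph 6.82-fold (2.77), Ret 8.60-fold (3.10) and Stmn2 3.06-fold (1.61), with Syt4 at 2.72. Apod was 3.60-fold higher (1.85, 1.53 to 2.18) and Uchl1 4.11-fold (2.04), and Gapdh had 0.60 without passing. Lower genes included Cryab (3.77-fold, -1.91), Sparc (5.71-fold, -2.51), Rpl39 (-1.16), mt-Nd2 (-4.26), mt-Co3 (-2.93) and Lztr1 (-11.3). Across 7587 genes 1275 were higher and 1147 lower. Counts by list were 16 of 20 higher for pan-neuronal markers (median 1.92), 23 of 32 for synaptic vesicle genes (2.17), 35 of 45 for the cytoskeleton (1.84), 11 of 18 for glycolysis (1.36) and 11 of 31 for the proteasome (0.88). All 13 mitochondrially encoded mRNAs were lower (-2.68). The other scalings gave 1088 higher and 1199 lower, 497 and 1489, and 5017 and 748.

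The test planned beforehand, edgeR's quasi-likelihood test on the 12 columns with Benjamini-Hochberg adjustment, passed more genes. It tests against no change and not against 1.5-fold, and it takes the columns as replicates, whose biological coefficient of variation was 1.67%. It called 642 genes higher and 1900 lower in the IP, 477 and 354 in input, 364 and 659 in the interaction, 3297 and 1630 for IP over input with the control virus, and 3912 and 1510 with shLarp1. With the columns counted as 1 sample per group, these counts compare single samples and not the conditions, and no p-value is given per gene for that reason.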

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

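All tests in this part were chosen after the results were seen. Changes in the IP and in input differed for 4 results, by amounts that were not tested across replicates.

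The low-ratio genes had medians of -0.48 in the IP, where 87.8% of them lay below 0, and 0.43 in input, with a median interaction of -0.90. In input 7 of 764 passed as higher and 5 as lower, and the level there follows the scaling. RNA of other cells carried into the control IP could lower markers of glia, fibroblasts, leukocytes and vessels alike. All 63 such markers had a median of -0.0392 in the IP (lower quartile -0.20), and the 6 vessel markers -0.24. Of the 63 markers, Mag, Fn1 and Sparc belonged to the low-ratio genes and had lower IP levels with shLarp1, without passing. Without these 3 the median was -0.0103. The other markers were not low-ratio genes. Median log2 ratios of IP to input by list were -0.405 (glia), -0.236 (fibroblasts), -0.0713 (macrophages) and 0.174 (vessels). Their IP levels therefore need not follow carried-over RNA, and the test cannot decide. It also covers RNA of other cells only. All 13 mitochondrially encoded mRNAs had IP values below 0 too (median -0.67). The ribosomal RNAs mt-Rnr1 (3220 to 2359 IP counts) and mt-Rnr2 (8606 to 5861) had fewer counts with shLarp1. Whether background RNA of any source was lower in the shLarp1 IP was not tested. If reads of 1 common kind were spread over the low-ratio genes, their input changes would vary less than those of other genes with like counts. The SDs were 0.244 and 0.3, a ratio of 0.814 (0.658 to 1 over resampled genes), which goes that way and leaves such reads open. A difference between single libraries and an effect of the knockdown cannot be told apart, since 1 library per group was counted.

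Most long non-coding genes were at 0 in input, 261 of 270 with at least 100 IP counts. Of those with at least 2000 IP counts 100% (51 of 51) had 0 counts in all input columns, among them Gas5 (13812 and 13772 IP counts) and Zfas1 (9833 and 7542), as had the ribosomal RNAs mt-Rnr1 and mt-Rnr2, against 0 of 934 protein-coding genes. The lower depth of the input is argued against, since the lowest input count expected of these genes at the protein-coding ratio was 230. Input may have been counted against a reference without long non-coding and ribosomal RNA genes, a hypothesis from the same data. Of genes with at least 2000 IP counts, 162 of 186 without a matched gene type were at 0 in input as well. Pseudogenes were at 0 only in part (7 of 12), so a lack of all non-coding genes would not describe the pattern fully. No biological explanation was tested.

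Apod was higher in the IP and close to its control level in input (interaction 1.51). The 44 other markers of fibroblasts, Schwann cells and satellite glia did not rise with it in the IP. Their median was -0.0268, and their upper quartile of 0.272 lay under the lower limit of Apod, 1.15. As said above, the IP levels of such markers need not follow carried-over RNA, so this cannot decide whether RNA of those cells raised Apod. Scaling is argued against, as the lowest log2 change over the scalings, filters, tests and left-out columns was 1.23. RNA of other cells and a difference between single libraries stay open beside an effect of the knockdown, with 1 library counted per group.

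The mitochondrially encoded mRNAs had medians of -0.67 in the IP (5 of 13 lower) and 0.29 in input (0 of 13 passing), with a median interaction of -0.89. Glycolysis genes had medians of -0.67 in input (3 of 18 lower, 15 not passing) and 0.06 in the IP (0 of 18 passing), with a median interaction of 0.83.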

How the results depend on the processing

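Alternatives added after seeing the data are those of the 1.5-fold rule and the percentiles outside the low-ratio and zero classes; the others were fixed beforehand, and where no cause is named the cause was not tested. Of genes past the planned edgeR test, the stricter filter, which tests fewer genes, left 1111 in IP, 1748 in IP over input with the control virus and 1944 with shLarp1, and limma-voom gave 1688 in IP; the other planned counts stayed within 1.5 times. Same-numbered columns correlated between -0.0451 and 0.0867 in 18 pairs. The highest were control IP with shLarp1 IP, at 0.0853 (number 1) and 0.0867 (number 3). If the columns are parts of 1 sample, such values can neither show nor exclude a pairing by number. With the number as a block the planned test called 2462 genes in IP, 831 in input, 1017 in the interaction, 4864 and 5352 for IP over input (944, 4644 and 5149 with the block within virus), and camera 42 tests. Fry, which asks whether a list's genes move 1 way, called 101.

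Under the 1.5-fold rule, genes passing in IP numbered 1066 without a filter, 80 with the stricter filter, 85 with a 2-fold bound and 145 without the low-ratio and zero classes. In input they numbered 216 (DESeq2 size factors), 160 (upper quartile), 211 (total counts), 49 (stricter filter), 54 (the 6 input columns alone) and 19 (2-fold), and 90 to 248 without 1 column; each of the 6 input columns had this effect because TMM then took an IP column as reference. In the interaction they numbered 119 (2-fold) and 166 (without the classes). For IP over input with the control virus they numbered 4027 (total counts), 1044 (stricter filter), 1300 (2-fold) and 1317 (without the classes), and with shLarp1 5765, 1403 and 1581 for the first 3 of these settings.

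For the named genes, calls were the same in 1593 alternatives, no longer passed in 157, newly passed in 27 and changed sign in 1; without 1 column these were 2406, 312, 47 and 3. Of 420 recomputed list medians 92 changed sign; 6 of these had lain in the outer 5% of random lists, with a counting interval on 1 side of 0. Without 1 column 233 of 1680 changed sign, 20 of them such medians. Larp1 in input passed under limma-voom (-1.24). Rpl39 over input with shLarp1 was 0.18 with total counts. Those 6 were the medians of the large ribosomal subunit in input (0.00212 with DESeq2 size factors), of cell cycle genes (0.383 and 0.63) and mitochondrial ribosomal proteins (0.688) over input with total counts, and of oxidative phosphorylation over input with upper-quartile factors (-0.407 and -0.397). Without 1 column, values ranged from -0.266 to 0.0695 for Apod in input (not called), -0.209 to 0.0515 for the large and -0.228 to 0.0366 for the small ribosomal subunit in input, and -0.445 to 0.0143 for synaptic vesicle genes in input. They ranged from -0.00404 to 0.0915 and -0.15 to 0.111 for oxidative phosphorylation over input with the control virus and shLarp1. Input depth limits what could be seen there: of genes changed 2-fold, the simulation recovered 7 of 50 in input and 26 of 50 in the IP.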

Other observations

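The test of the ribosomal protein hypothesis below was chosen after the results were seen; the gene lists had been fixed before the data were examined. In control neurons, single chaperone and stress-response mRNAs were higher in the IP than in input, where the median of all genes was 0.38. Hsp90aa1 was 9.56-fold higher (log2 3.26, 2.84 to 3.71), Hsph1 5.45-fold (2.45), Hspa8 4.39-fold (2.13, 2.04 to 2.23), Hsp90ab1 3.08-fold (1.62) and the phosphatase gene Dusp1 3.08-fold (1.62). These were the 5 of 16 heat shock and immediate early genes that passed, with a list median of 0.60 at percentile 91.96 of random lists (82.55 outside the low-ratio class) and 5 members below 0. In the stress and unfolded protein response list 5 of 25 were higher: asparagine synthetase (Asns, 2.82, 1.83 to 4.04), Chac1 (2.16), the endoplasmic reticulum chaperones Hspa5 (2.14) and Hsp90b1 (1.93), and calreticulin (Calr, 1.27). That list lay at percentile 97.79 (94.84 outside the class). In the IP none of the members of these lists passed between the viruses.

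Genes of cholesterol synthesis went both ways in IP over input with the control virus. Squalene epoxidase (Sqle, 3.26, 1.90 to 5.15), Hmgcs1 (2.39) and Idi1 (1.92) were higher, and Msmo1 (-4.52, -4.60 to -4.44) and the transcription factor gene Srebf2 (-2.52) were lower. The latter both belonged to the low-ratio genes.

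Larp1 binds TOP mRNAs, and a lower ribosome-bound share of ribosomal protein mRNAs after knockdown was put as a hypothesis. Binding alone does not set this direction. The IP over input ratio stands in for that share only roughly. Background RNA is part of the IP, input is not limited to the tagged neurons, and the references may have differed. The median change of the IP over input ratio was 0.03 for large-subunit and 0.06 for small-subunit protein mRNAs. The former lay at percentile 93.84 of matched lists (28.73 outside the low-ratio class) and the latter at 96.62 (60.9), inside the range of such lists, so the hypothesis is not borne out and stays open. Outside that class the large-subunit list lay low both in the IP (percentile 0) and in input (0.38). Glycolysis lay low there in input as well (0.01).

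Other splits of the columns gave fewer genes past the planned test than the real split. In fits of the 6 columns of 2 groups the real split called 3209 genes in IP, 941 in input, and 4595 and 4549 for IP over input, against highest other values of 0, 2, 0 and 0; 1 of 10 splits reached the real value each time, and 10 splits are too few for a share under 0.05. In the interaction 1 of 100 splits reached the real value of 1023 (highest other 199). If the columns are parts of 1 sample, such splits compare samples and not viruses. Every other split then mixes the samples, and the real split would call the most genes in any case. The splits therefore cannot exclude chance.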
